A study of Drosophila melanogaster with 2 samples.

How the data were processed

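The samples were 2 biological replicates of whole embryos of Drosophila melanogaster aged 0 to 24 h that carried an ssp-eGFP fusion, immunoprecipitated with an anti-GFP antibody after sonication to a size range of 200 to 800 bp. Per the labels they form 1 group, ssp-eGFP embryo. A control library is named in the labels and is not analysed here. The authors called peaks on the dm6 assembly from the alignments of each replicate and of both, each with a control, and ranked them by the irreproducible discovery rate (IDR). The peak caller and aligner are not given in the sources used here.

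The deposited signal is the value the peak caller assigned to each peak, with no scaling between lists stated, and was used to describe and rank peaks within a list. Signals of the replicates were also set side by side as log2 ratios, which include any difference in scale between their lists. The deposited score is the IDR score of each peak, capped by its construction, and the ranked lists also hold a score equal to minus log10 of the global IDR, which was used to find candidates at or under an IDR of 0.01. The thresholded lists derive from 1 further file whose kind the deposited notes do not state. Another 16 columns of the ranked lists of the whole series could not be assigned to a sample and were not used. Depth is unknown, since no counts are in the lists, so no precision from counting is given.

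Comparisons, alternatives, gene lists, motifs and the rule for named genes were written before the data were examined. The combined list was the main peak set. The background was the failing candidates: ranked candidates on 2L, 2R, 3L, 3R, 4 and X that overlapped no thresholded list. Of these 120106, 115 had an IDR at or under the threshold, and the promoter comparison was repeated without them. The chromosome comparison also took in the peaks and failing candidates on Y and the unplaced scaffolds. Summits were assigned to the nearest TSS of the Ensembl annotation, release 115, with a window of 500 bp, and otherwise to 5' UTR, coding exon, 3' UTR, other exon, intron or intergenic sequence in that order. Coordinates count from 1.

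Replicate overlap was a shared base, tested by 100000 circular shifts of replicate 2 along each arm. Shares were compared by two-sided Fisher's exact tests with Woolf 95% intervals, adding 0.5 where a cell was 0, and p-values were recorded down to 1e-300. Benjamini-Hochberg correction was applied within each family, over the classes, chromosomes, 28 gene lists, 32 motifs or 2080 6-mers, at 0.05. Signal medians were compared by 100000 permutations. Gene lists were tested among protein-coding genes with a candidate within 500 bp of a TSS. Motifs and 6-mers were sought on both strands within 50 bp of the summit, against failing candidates matched at up to 5 for 1 on GC content in bins of 5 percentage points and on TSS status. The pool ran out in AT-rich bins, and 18647 candidates were drawn for 4914 peaks.

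The named genes were ssp, the 25 peaks with the highest signal among those overlapped in both replicate lists, up to 4 members with the highest signal of each gene list past the threshold, any member with a peak, up to 4, in depleted or silent lists, the motifs past the threshold and the 10 6-mers with the largest odds ratio. A peak was named by the protein-coding gene with the nearest TSS within 500 bp, and otherwise by the gene it lay in or the nearest gene. Genes named outside this rule are said to be so.

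The alternatives were the conservative list, the list of each single replicate, the stronger peaks (those above the median signal), windows of 200 and 1000 bp, 50% reciprocal overlap, summits within 100 bp, random positions at 10 per peak, all protein-coding genes, the nearest TSS only, the flanks of the same peaks centred 500 bp away, 100 bp each side of the summit and no matching. Added after the data were seen were the background without candidates past the IDR threshold, and common odds ratios over strata of GC content and TSS status by the Cochran-Mantel-Haenszel method for motifs and 6-mers. Overlap with transposable element families was looked at once during exploration and is not reported. The comparison of failing candidates between regions was taken to decide only where at most 10% of the candidates of a region had passed. Bootstrap intervals in the closing part used 2000 draws.

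The tests were tested on simulated data. The planted motif, both planted 6-mers and the planted gene list were called, with 0 other lists and 0 unrelated motifs called. In the 6-mer test 4 other 6-mers were also called with an odds ratio above 2. Both sets of windows in the motif and 6-mer simulations were drawn at random from the same candidates, without matching. The simulations therefore do not cover false calls from incomplete matching on GC content and TSS status. The motif was planted in 10% of the windows of 1 set, so recovery of rarer motifs was not simulated. Genes were drawn as bound independently of each other, so false calls from neighbours that share a peak are not covered either. Of 40 unrelated pairs of peak lists, 1 had a shift p under 0.05. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.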

Results

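Chromatin immunoprecipitation followed by sequencing was used to map where a sunspot (ssp) protein fused to enhanced green fluorescent protein sat on the genome of Drosophila melanogaster. The immunoprecipitation used an antibody against the fluorescent protein, and the material was whole embryos collected over 0 to 24 h, so every tissue and stage of embryogenesis was pooled. The labels give 1 group, ssp-eGFP embryo, with 2 biological replicates and no other condition. The data were peak lists on the dm6 assembly, and the sequencing depth is unknown because the lists hold no read counts. The questions that this design allows were where the peaks lay, which genes and sequences they marked, and how far the replicates shared them.

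The combined list, made by the authors from both replicates, held 4948 peaks with a median width of 416 bp that covered 1809.53 kb. The ranked candidates, most of which failed the threshold, had the same median width, so this width does not set the peaks apart. Of the 4948 entries, 18 repeated the interval of another. Its conservative version held 4719 peaks, and replicates 1 and 2 on their own gave 3606 and 3437 peaks. Peak signal, the value the peak caller gave to each peak, had a median of 132.934 in the combined list and ranged from 2.02 to 6042. A set of 160 peaks had a signal under 20. Of the combined peaks, 2782 (56.2%) overlapped a peak in both replicate lists and 963 (19.5%) overlapped neither.

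Most regions bound in replicate 1 were bound in replicate 2. Of the 3594 replicate 1 peaks on the chromosomes 2L, 2R, 3L, 3R, 4 and X, 2754 (76.6%, Wilson 95% interval 75.2 to 78.0%) overlapped a replicate 2 peak, and 2791 of 3408 (81.9%) replicate 2 peaks overlapped a replicate 1 peak. Strong regions were shared almost completely: the share rose from 39.6% in the lowest signal quartile of replicate 1 to 99.6% in the highest. Circular shifts of the replicate 2 peaks along each arm gave a mean of 1.71% and a maximum of 17.9% (one-sided permutation test, p = 1e-05, the smallest these draws can give). The shift test treats peaks, not embryos, as its units, so its p-value is not evidence across biological replicates. Shifts also move peaks away from transcription start sites. Within 500 bp of such a site lay 56.4% of replicate 1 and 56.8% of replicate 2 summits, against 13.7% of random positions. The p-value therefore does not separate shared sites from a shared preference for start sites.

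Among 2655 pairs of overlapping thresholded peaks the signals of the replicates ranked alike, with a Spearman rho of 0.911 (95% interval 0.904 to 0.918). The median log2 ratio of replicate 2 to replicate 1 was -0.21 with an SD of 0.37 across pairs, and this ratio includes any difference in scale between the lists. Over all 51904 overlapping pairs of ranked candidates, which include those that failed the threshold, rho was 0.443 (0.436 to 0.451). These correlations are across peaks, which are not independent replicates.

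**Figure D1:**
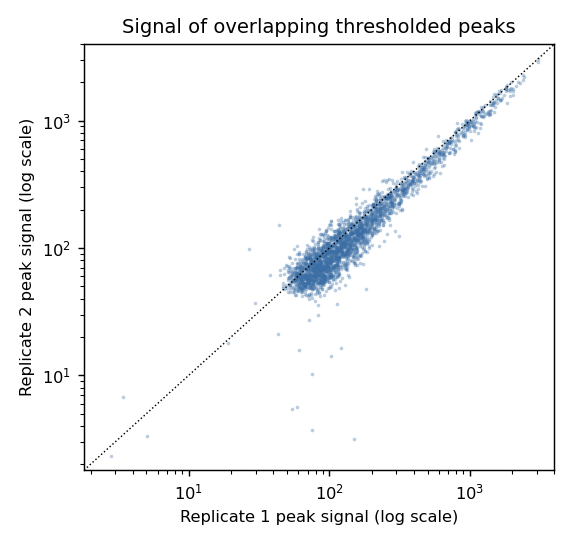
Signal of each of the 2655 pairs of overlapping thresholded peaks in replicate 1 (x axis) and replicate 2 (y axis), both on log scales in the peak caller's own unit, with 1 point per pair and a dotted line at equal signal. The pairs follow the line, with a Spearman rho of 0.911.

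The strongest ssp peaks lay just upstream of protein-coding genes. The highest signal, 6042, was at l(3)80Fg (FBgn0287183, 3L from 26013583 to 26014502), with its summit 118 bp upstream of the transcription start site (TSS). It was followed by 5928 at MED21 (FBgn0040020, 3L from 25115728 to 25116299), a subunit of the Mediator complex, by 4671 at CG40045 (FBgn0058045, 3L from 24028190 to 24028677) and by 4621 at Gyf (FBgn0039936, chromosome 4 from 866862 to 867383). Clamp (FBgn0032979, 2L from 22169035 to 22169532), which encodes a zinc-finger protein of dosage compensation, had a signal of 4478 with the summit 117 bp upstream.

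The other peaks among the strongest 25 were at dmpd, the mitochondrial fission gene Fis1, the lipoprotein gene apolpp, the respiratory chain genes ND-AGGG and UQCR-11, Hcf, d4, CG14464, the exosome gene Rrp42, the stress sensor Ire1, the adaptor gene Crk, RNASEK, the ribosome maturation kinase RIOK2, Alg-2, CG40228, bdg, the axon guidance receptor gene PlexB, CG17883, Rnf11 and the histone kinase gene Haspin. Their signals ran down to 3342 at Rnf11. Of the 25 summits, 24 lay within 500 bp of a protein-coding TSS, and 23 of these 24 lay upstream of it. The summit farther away was that of Haspin (FBgn0046706, 2R from 4012567 to 4013066), an intergenic peak 1309 bp upstream of the TSS. The Rrp42 peak also lay within 500 bp of the TSS of the proteasome gene Prosbeta1, a gene named after its values were seen. All 25 were among the strongest 100 peaks of each replicate, and the median log2 ratio of their replicate 2 to replicate 1 signals was -0.12 with an SD of 0.11 across the 25. The 25 were selected on the combined signal, which largely sets these ranks. They held combined ranks 1 to 25, so the demand for a peak in both replicate lists removed none. Whether the selection also lowered this SD was not tested.

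No peak lay at the tagged gene itself in the thresholded lists. Within 2000 bp of ssp (FBgn0036248, 3L from 12118257 to 12119789) the combined, conservative and replicate lists held 0 peaks, and the nearest combined peak was 5181 bp away. Replicate 1 had 8 unthresholded candidates in this window with signals from 3.11 to 48.0 and a smallest irreproducible discovery rate (IDR) of 0.264, and replicate 2 had none.

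ssp peaks were concentrated at transcription start sites. Of 4914 combined summits on the 6 chromosome arms, 2459 (50.04%) lay within 500 bp of an annotated TSS of any gene type, protein-coding or not. The share was 15179 of 120106 (12.6%) among candidates that failed the threshold and overlapped no thresholded list. The odds ratio was 6.92 (95% interval 6.53 to 7.34, two-sided Fisher's exact test, p = 1e-300, the smallest value recorded), and 10.4 with a window of 200 bp and 10.9 among the stronger peaks. The summits sat upstream of the start: their median position was -89 bp and 2024 of the 2459 (82.3%) were upstream, whereas the failing candidates near a TSS had a median of 79 bp and 39.96% upstream. In the top signal decile the share upstream was 90.1%.

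**Figure D2:**
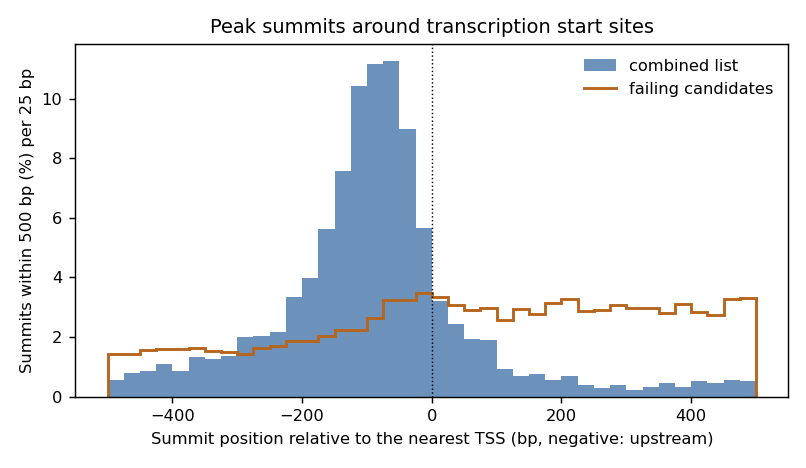
Summit position relative to the nearest annotated TSS of any gene type in bp (x axis, negative values upstream) and the percent of the summits within 500 bp that fall in each bin of 25 bp (y axis). Filled bars are the 2459 combined-list summits, which pile up upstream of the start with a median of -89 bp, and the line is the 15179 failing candidates.

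Of the annotation classes, coding exons had the lowest share of peaks relative to the background. Coding exons held 111 summits (2.26%) against 21.4% of the failing candidates (odds ratio 0.0848, 95% interval 0.0702 to 0.102, Fisher adjusted p = 3.5e-300). Introns held 1480 (30.1% against 36.9%, odds ratio 0.738) and intergenic sequence 767 (15.6% against 25.5%, odds ratio 0.541), and both were below the background (Fisher adjusted p = 3.95e-22 and 2.53e-60). The 5' UTR with 21 summits (odds ratio 0.471) and the 3' UTR with 35 (odds ratio 0.379) were also below it (Fisher adjusted p = 0.000206 and 5.77e-11). Other exons, with 41 summits, did not pass the threshold (odds ratio 0.996, Fisher adjusted p = 1).

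Peaks at a TSS were also the stronger ones. Their median signal was 166 (quartiles 105 and 352, n = 2459), against 112 (81.7 and 178, n = 2455) elsewhere, a difference of 54.7 (two-sided permutation test, p = 1e-05, the smallest these draws can give). The share of summits at a TSS was 34.8% in the lowest signal decile, 31.2% in the decile above it and 84.3% in the highest. The difference was smaller in the lists of single replicates, whose signals are lower: 26.6 without replicate 1 and 29.7 without replicate 2.

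Chromosome 4 had few failing candidates and about the share of peaks that its length gives. It makes up 1.01% of the length of the 6 arms and held 1.22% of their peaks (60, or 44.5 per Mb against 36.7 per Mb over all 6) but 0.0849% of the failing candidates (102, or 75.7 against 897 per Mb). Its odds ratio against failing candidates, here with those on Y and the unplaced scaffolds, was 14.9 (95% interval 10.8 to 20.6, Fisher adjusted p = 1.79e-41), 23.1 without replicate 1, 19.9 without replicate 2 and 26.6 among the stronger peaks, and it reflects mostly the scarcity of failing candidates. On the 6 arms alone the combined-list odds ratio of chromosome 4 was 14.5. The arm 3L was also above the background (1081 peaks, odds ratio 1.21, Fisher adjusted p = 2.6e-07), and 3R (1050 peaks, odds ratio 0.814, adjusted p = 8.73e-09), Y (5 peaks, odds ratio 0.155, adjusted p = 2.25e-08) and the unplaced scaffolds (29 peaks, odds ratio 0.215, adjusted p = 2.26e-26) were below it. The arms 2R and X did not pass the threshold (odds ratios 1.04 and 1.03, Fisher adjusted p = 0.391 and 0.507). The arm 2L passed it (877 peaks, odds ratio 1.09, Fisher adjusted p = 0.0315), but not in the conservative list, among the stronger peaks or without replicate 1. Without replicate 2, Y held 0 peaks (odds ratio 0.0213) and the unplaced scaffolds 12 (0.122). Some candidates past the IDR threshold were absent from the combined list, 81 on the unplaced scaffolds, 59 on 3R and 0 on chromosome 4 and Y. The peak counts do not include them. On the unplaced scaffolds they outnumber the 29 peaks, so the low odds ratio there cannot be separated from their absence.

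Of the strongest 25 peaks, 6 lay on chromosome 4, 9 on 2R, 6 on 3L, 3 on 3R, 1 on 2L and 0 on X. Chromosome 4 and the 5 Mb at the centromeric end of each other arm, regions defined after the positions of the strongest peaks were seen, together held 643 peaks and 18 of the 25. The 60 peaks of chromosome 4 had a median signal of 1006, with 66.7% in the top signal decile, and the 583 at the centromeric ends had one of 157, with 19.2%, against 130 and 7.96% for the 4271 peaks elsewhere. For both kinds of region together, 152 peaks against 340 elsewhere were in the top decile (odds ratio 3.58, 95% interval 2.89 to 4.43, two-sided Fisher's exact test, p = 3.6e-28), and for the centromeric ends alone the odds ratio was 2.75. Because the regions were chosen from these peaks, this p-value does not count as an independent test.

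**Figure D3:**
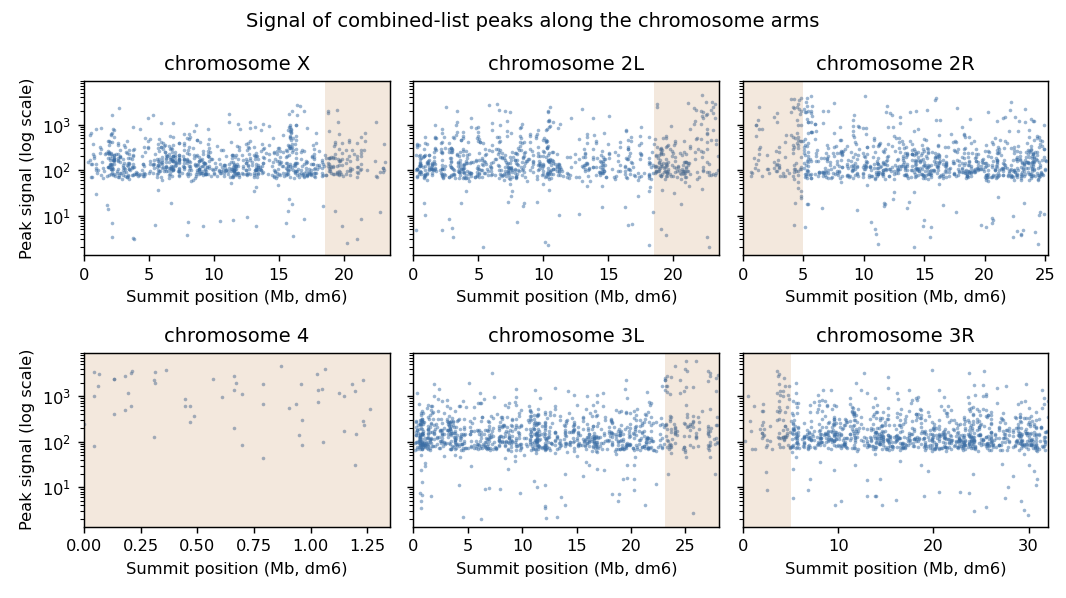
Peak signal on a log scale (y axis) against summit position in Mb on dm6 (x axis) for the combined-list peaks on each of the 6 chromosome arms. Each point is 1 peak, and the shaded parts are chromosome 4 and the 5 Mb at the centromeric end of the other arms, whose median signals were 1006 and 157.

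Genes of cytosolic ribosomal proteins, architectural and promoter-binding proteins, general transcription, the spindle and kinetochore and cell cycle control had a peak more often than other genes. Of 10362 protein-coding genes with a candidate within 500 bp of a TSS, 2984 (28.8%) had a combined peak there. Cytosolic ribosomal protein genes had a peak in 59 of 83 cases (71.1%, odds ratio 6.18, 95% interval 3.84 to 9.95, Fisher adjusted p = 4.18e-14), led by RpL5 (signal 3116), RpS3A (3113), RpL15 (2849) and RpL38 (2469). RpS3A lies on chromosome 4 and the others in the 5 Mb at a centromeric end. In these regions 42.2% of peaks at a TSS were in the top signal decile, against 13.4% elsewhere, so these high signals are not particular to the list. Genes of architectural and promoter-binding proteins had a peak in 16 of 24 (odds ratio 4.97, 95% interval 2.12 to 11.6, Fisher adjusted p = 0.000732), with Clamp at 4478, the chromodomain gene Chro at 1681, the insulator gene Cp190 at 564 and the dosage compensation helicase gene mle at 475.

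General transcription and RNA polymerase II genes had a peak in 20 of 34 (odds ratio 3.55, 95% interval 1.79 to 7.04, Fisher adjusted p = 0.00179), among them Polr2H (650), Polr2J (555), Taf7 (516) and Taf5 (504). Spindle and kinetochore genes had one in 29 of 54 (odds ratio 2.89, 95% interval 1.69 to 4.94, Fisher adjusted p = 0.000732), with Grip71 of the gamma-tubulin complexes at 2827, the kinetochore gene Nuf2 at 2010, the centriole duplication kinase gene SAK at 1257 and the centriole gene asl at 1182. Cell cycle control genes had one in 15 of 29 (odds ratio 2.66, 95% interval 1.28 to 5.51, Fisher adjusted p = 0.0415). Its strongest members were the checkpoint kinase genes mei-41 (2721) and tefu (2628) and the cyclin genes CycK (1023) and CycD (687). The tefu summit lay closer to the TSS of Hsc70-4, 137 bp upstream of it against 314 bp for tefu, a gene pair noticed after its values were seen. When each peak counted only for the gene with the nearest TSS, the calls of the general transcription (odds ratio 2.37, Fisher adjusted p = 0.0853), spindle (2.08, adjusted p = 0.0853) and cell cycle (2.34, adjusted p = 0.124) lists were lost, and without replicate 2 those of the spindle (2.00) and cell cycle (2.55) lists (both adjusted p = 0.0567). The cell cycle call was lost in 6 of 8 alternatives and the spindle call in 3.

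The 3 lists that passed the threshold with fewer peaks than other genes were those written as silent or late controls. Chemosensory receptor genes had a peak in 2 of 117 (odds ratio 0.0424, 95% interval 0.0105 to 0.172, Fisher adjusted p = 9.53e-14), at Ir60b (312.8) and Ir60e (72.0), of which the Ir60e peak overlapped neither replicate list. When each peak counted only for the gene with the nearest TSS, this list had 0 of 117, so both peaks were assigned to another protein-coding gene. Cuticle protein genes had 0 of 51 (odds ratio 0.0238, 95% interval 0.00147 to 0.386, Fisher adjusted p = 4.68e-07). With a window of 1000 bp these odds ratios were 0.103 and 0.0838. Testis-enriched genes had 0 of 15 (Fisher adjusted p = 0.0348), a call lost in 5 of 8 alternatives, and the interval of its odds ratio, with 0.5 added to each cell, reached 1.33.

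The other 20 lists did not pass the threshold. Their shares with a peak were 9 of 18 germline genes, 13 of 27 splicing factors, 14 of 30 Polycomb and trithorax genes, 7 of 16 heat shock genes, 12 of 28 proteasome genes, 18 of 43 translation factors, 26 of 63 mitochondrial ribosomal protein genes, 24 of 62 respiratory chain genes, 8 of 21 muscle genes, 14 of 38 DNA replication genes and 4 of 11 gut genes. They were 3 of 11 E(spl) complex genes, 3 of 21 dorsoventral genes, 3 of 26 neural genes, 2 of 21 segmentation genes, 1 of 15 tracheal and epidermal genes, 1 of 16 early zygotic genes, 0 of 11 hemocyte genes, 0 of 4 Hox genes and 0 of 1 replication histone gene. Their adjusted p-values ran from 0.0970 to 1. Mitochondrial ribosomal protein genes passed the threshold among all protein-coding genes, among the stronger peaks and without replicate 1 (odds ratios 2.04, 2.13 and 2.04), and translation factors among all protein-coding genes, with a window of 1000 bp and in the conservative list (2.01, 2.10 and 2.45). Among all protein-coding genes, splicing factors (2.82) and Polycomb and trithorax genes (3.03) also passed, and replication histone genes (0 of 111, odds ratio 0.0163, Fisher adjusted p = 2.75e-11) and hemocyte genes (0 of 18, 0.0991, adjusted p = 0.0428) were depleted. Only 1 of the 111 histone genes had a candidate, so at most 1 could have had a peak. Their depletion was fixed in advance and says nothing about binding. Germline genes passed with a window of 1000 bp (3.05), and segmentation genes were depleted in the conservative list (0.128). Neighbouring genes share peaks, so members of a list are not independent, and the p-values are across genes, not replicates. Candidates at mor of the trithorax list and ATPsynC of the respiratory chain list, named after their values were seen, passed the IDR threshold without being in the combined list.

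**Figure D4:**
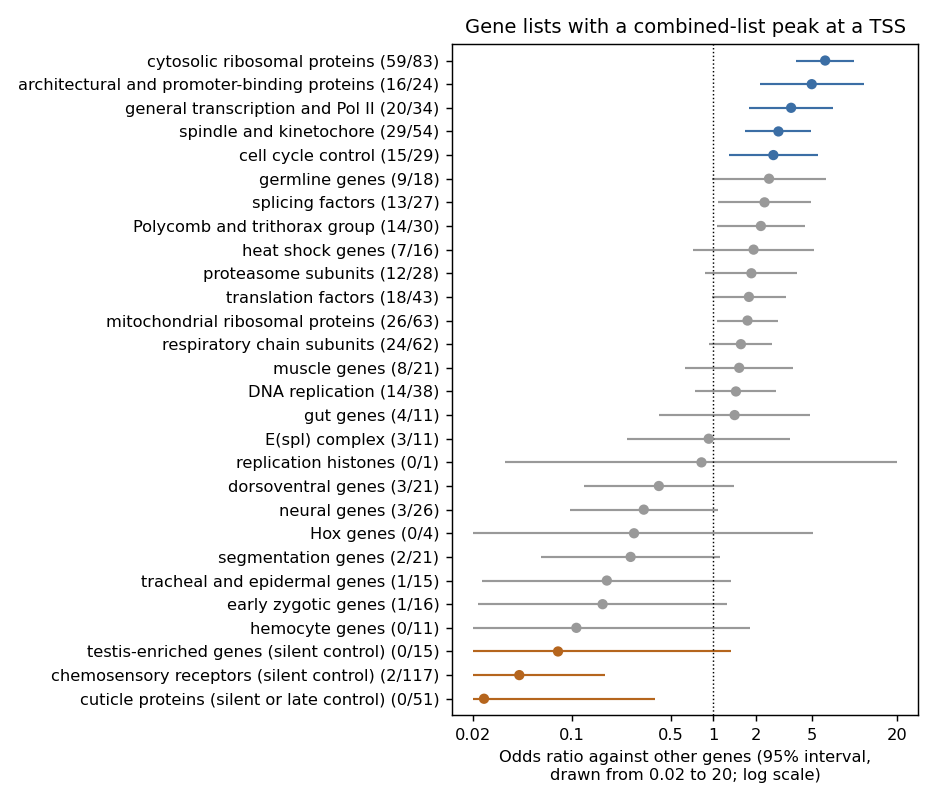
Odds ratio of having a combined-list peak within 500 bp of a TSS, members of each of 28 gene lists against other protein-coding genes with a candidate (x axis, log scale, lines are 95% intervals drawn from 0.02 to 20). The fractions are members with a peak over members with a candidate, blue and brown mark the 5 lists above and the 3 below at adjusted p under 0.05, and grey the other 20.

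Some core promoter sequences, but not all, were found near ssp summits more often than near failing candidates. The DRE, the site of the promoter factors DREF and BEAF-32, lay within 50 bp of 2.83% of summits against 0.853% of matched candidates (odds ratio 3.38, 95% interval 2.69 to 4.26, Fisher adjusted p = 3.56e-22). Its core CGATA was at 18.8% against 11.9% (odds ratio 1.71, Fisher adjusted p = 1.04e-32). Ohler motif 6 (odds ratio 1.94), Ohler motif 1, the site of M1BP (1.90), Ohler motif 7 (1.72), the TATA box (1.44), the homeodomain site (1.19) and the GATA site (1.16) were also more frequent, with adjusted p from 5.6e-18 for the TATA box to 0.00623 for the homeodomain site. Poly-CA (odds ratio 0.429), the Tramtrack core (0.550), GAGA (0.601), the PHO core (0.688) and poly-A (0.851) were less frequent, with adjusted p from 3.52e-18 to 0.0206. The other 19 motifs did not pass the threshold, among them the core promoter elements Initiator (24.2% against 25.2%, odds ratio 0.949) and Ohler motif 5 (0.993), named after their values were seen. Both passed it in either direction elsewhere: Initiator at 1.25 without matching and 0.877 without replicate 2, Ohler motif 5 at 1.16 within 100 bp and 0.833 without matching.

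Matching was incomplete, because the pool of AT-rich failing candidates ran out: the median GC content was 35.8% in the peaks and 38.3% in the matched set, and 50.04% against 34.8% lay at a TSS. In an alternative chosen after seeing this, a common odds ratio over strata of GC content and TSS status, DRE (2.73), CGATA (1.59), Ohler 7 (1.65), Ohler 1 (1.61), Ohler 6 (1.47) and the TATA box (1.24) kept their calls. The GATA, homeodomain and GAGA calls ended there (Cochran-Mantel-Haenszel chi-square test, adjusted p = 0.0947, 0.525 and 0.0867). GATA went from 1.16 (95% interval 1.07 to 1.25) to 1.09 (1.01 to 1.18), the homeodomain site from 1.19 (1.07 to 1.33) to 1.05 (0.940 to 1.18) and GAGA from 0.601 (0.411 to 0.879) to 0.667 (0.461 to 0.966). GAGA turned to 1.17 within 100 bp of the summit, and poly-A to 1.21 against the flanks of the same peaks and 1.86 without matching. Ohler 1 was at 1.01 and Ohler 6 at 1.55 among the stronger peaks (Fisher adjusted p = 1 and 0.0599), but Ohler 1 was at 3.33 within 100 bp of the summit. Against the flanks and without matching, the odds ratios were larger for DRE (10.2 and 12.4), Ohler 1 (25.5 and 6.49) and Ohler 6 (3.68 and 5.44).

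**Figure D5:**
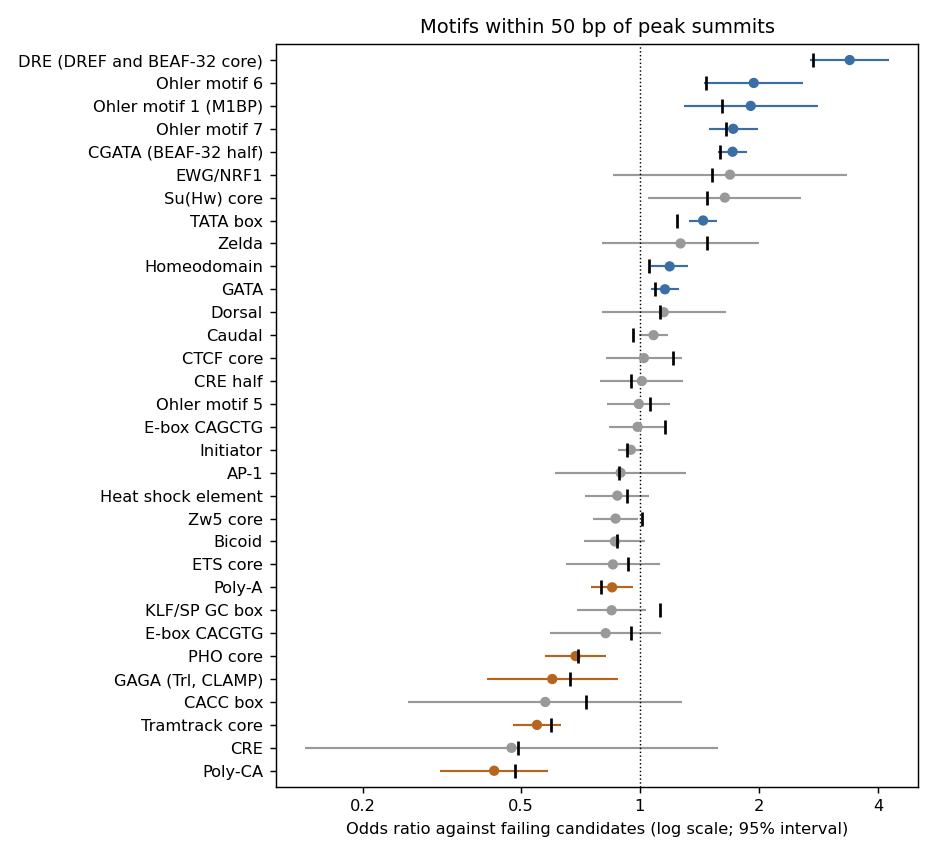
Odds ratio of each of 32 motifs within 50 bp of combined-list summits against matched failing candidates (x axis, log scale, points with 95% interval lines), with black ticks for the common odds ratio over strata of GC content and TSS status. Blue and brown mark the 8 motifs above and the 5 below at adjusted p under 0.05, and grey the other 19, with the DRE highest at 3.38.

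In the unguided search over 2080 6-mers, some of the most enriched words shared bases with the DRE and others did not. CGATAG was the most enriched (7.04% against 2.87%, odds ratio 2.56, 95% interval 2.23 to 2.94, Fisher adjusted p = 4.93e-34), followed by TATCGA (2.21), ATCGAT (1.99), CGCTAG (1.90), ATATCG (1.87), ACAGTG (1.82), ACACTG (1.81), CACTAG (1.73), CGATAC (1.72) and ATATTA (1.71). In all, 336 6-mers were more frequent and 570 less frequent at adjusted p under 0.05. Over strata of GC content and TSS status the counts were 262 and 257, so the larger number of depleted words was not kept. All 10 named words passed the threshold in strata and against the flanks of the same peaks. Overlapping words share sites and are not independent.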

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

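The tests on the left-out candidates, the regions of the strongest peaks and the split of the raised signal test between them were chosen only after the results were seen, as was the test of neighbouring genes on the ribosomal protein list. No biological explanation was tested for any of these patterns, since the design gives 1 group.

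A signal appeared in data that the comparisons did not use: 198 ranked candidates had an IDR at or under the threshold of the combined list without being in it, 3.85% of the 5146 candidates past the threshold. On the main arms 117 of them lay in 68 clusters, and 48 lay within 500 bp of a protein-coding TSS. Of the 117, 59 were on 3R. The other 81 lay on the unplaced scaffolds, which held 29 of the 4948 combined peaks. The strongest, named after their values were seen, were at kibra (signal 3047), mor (2839), ifc (2684), ATPsynC (2444), Maf1 (2392) and CG6051 (1755). Removal of fixed genome regions from every thresholded list is a candidate explanation that stays open: 1.01% of them overlapped any thresholded list and 62.1% or more overlapped the candidates left out of each other list, but the explanation was framed from these overlaps, the set was defined by absence from a thresholded list, and another filter common to the lists could give the same. Removal of weak peaks is argued against. Of the 198, 99 had a signal above the median of the combined list, which itself kept 160 peaks with a signal under 20. A cut on signal cannot account for those 99. The bound set for excluding this explanation was not met: the median signal of the left-out candidates was 133 (bootstrap interval 116 to 148), above the lower quartile of the combined list (89.2), while the bound was the list median (132.934), which lies inside the interval.

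Strong peaks were over-represented near centromeres and on chromosome 4, with 18 of the strongest 25, although 340 of the 492 peaks in the top signal decile lay elsewhere. At the centromeric ends a generally raised signal, as copy number or mappability might give, is argued against, since 3.61% of candidates passed there (3.93% elsewhere) and the failing ones had a lower median signal than elsewhere (ratio 0.902, bootstrap interval 0.888 to 0.918). On chromosome 4 it cannot be told apart from stronger binding: the ratio was 0.908 (0.809 to 1.13), but 37.0% of its candidates had passed, so the failing ones are a selected remainder. AT-rich sequence as the whole cause is argued against too: among peaks at a TSS, the common odds ratio of being in the top signal decile was 4.69 within GC bins (95% interval 3.59 to 6.13), 4.72 before, and 3.595 (2.68 to 4.83) without chromosome 4. Over all peaks, without GC bins, the odds ratio for both kinds of region was 3.58 in the combined list, 4.51 in the replicate 1 list and 4.03 in the replicate 2 list, and what sets the regions apart stays open, as the control library was not analysed here.

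Ribosomal protein genes had more peaks than other genes. Counting of 1 peak for several neighbours is argued against, since the odds ratio was 8.56 (95% interval 5.37 to 13.7) when each peak counted for the nearest TSS only. Signal gained from strong transcription may contribute and cannot be told apart from specific binding: the median signal of peaks at these genes was 198 against 167 at other protein-coding TSSs, a difference of 31.6 (two-sided permutation test, p = 0.182), and no expression data or untagged control entered the comparison. It was also not adjusted for the regions near centromeres and on chromosome 4, where the peaks at RpL5, RpS3A, RpL15 and RpL38 lie.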

How the results depend on the processing

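Promoter share, replicate overlap, signal by class, list sizes, the number of chromosomes past the threshold and the count of enriched 6-mers kept their direction and threshold side, or stayed within 1.5 times, under each alternative run, but the 2L call was lost in 3 of 4. The promoter odds ratio ranged from 4.76 to 10.9. The background without candidates past the IDR threshold and the stratified tests were added after the data were seen. Depth is unknown, replicate overlap needs both replicates, and single-replicate lists rest on 1 library each. No paired analysis was possible because there was 1 group. The cause of the changes below was not tested, except that the thresholded and all-gene settings change which peaks or genes enter.

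Signal correlation was 0.506 with summits within 100 bp and 0.911 for thresholded peaks only. Enriched gene lists numbered 2 with the nearest TSS only and 9 among all protein-coding genes, and ranged from 3 to 5 when a replicate was left out. Depleted lists numbered 5 among all protein-coding genes, including the replication histones, where only 1 of 111 genes had a candidate. Without matching, 13 motifs were enriched and 12 depleted. Depleted motifs numbered 9 within 100 bp of the summit, 8 against the flanks and 8 when either replicate was left out. GAGA reversed to 1.17 within 100 bp, and poly-A to 1.21 against the flanks and 1.86 without matching. Besides these reversals, the GATA, homeodomain and GAGA calls were each lost in 2 alternatives, and the poly-A, Ohler 1 and Ohler 6 calls in 1 each. The cell cycle call was lost in 6 of 8 alternatives, spindle in 3, general transcription in 1 and testis-enriched in 5, while mitochondrial ribosomal proteins and translation factors each gained a call in 3.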

Other observations

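All tests in this part were chosen only after related results were seen. The words came from scans of all chromosomes, so the chromosomes held out below were not fully unseen.

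Small nuclear RNA genes had a combined peak within 500 bp of a TSS in 8 of the 18 with a candidate (44.4%). Shares were lower for small nucleolar RNA genes (14 of 123, 11.4%), transfer RNA genes (10 of 132, 7.58%) and other non-coding RNA genes (212 of 2192, 9.67%), and 28.8% for protein-coding genes. The differences were not tested, and such genes can share a promoter peak with a neighbour. E2f1 and PCNA were picked, after their values were seen, from single genes that also included Dref, BEAF-32, M1BP, Clamp, CycE, Dp, E2f2, arm and wg. Of these, Clamp (signal 4478), Dp (370), BEAF-32 (216), CycE (215) and M1BP (147) had a combined peak within 500 bp of a TSS. Dref, E2f2, arm and wg are not reported here. E2f1, a regulator of the cell cycle, had no combined peak within 500 bp of a TSS, the nearest summit being 3234 bp away. Only replicate 1 had an unthresholded candidate in that window, with a signal of 11.6 at percentile 36.0 of its candidates. PCNA, the replication clamp gene, had none either (5327 bp), but 2 unthresholded candidates, the stronger with a signal of 49.3, at percentile 90.1 of the ranked candidates. Both replicates also had a candidate within 500 bp of its TSS. The strongest were at percentile 75.7 of the replicate 1 candidates and 89.3 of the replicate 2 candidates.

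Strong peaks may carry a longer sequence word than the 6-mers. Words were chosen in the 1198 stronger peaks of 2L, 3L and X outside the centromeric ends. Among 8-mers found in at least 15 of these peaks, GTGTGAAC was the most enriched when ranked by p-value. It was tested in all 1035 stronger peaks of 2R, 3R and 4, centromeric ends included, where 1.55% had it against 0.194% of failing candidates (common odds ratio 5.32 within strata of GC content and TSS status, 95% interval 2.56 to 11.1, chi-square test, p = 1.57e-07). Of the 10 words chosen in this way 6 passed in the held-out arms, GTGTGAAC, GTGGAAAC, ACTATCGA, AGTGAGAA, AACTATCG and ATCGATAG, several of which overlap the DRE core. More copies of GTGTGAAC near centromeres and on chromosome 4 were not shown: among peaks at a TSS its odds ratio there against elsewhere was 1.30 (95% interval 0.539 to 3.11, two-sided Fisher's exact test, p = 0.621), which leaves the question open.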
